A study of Mus musculus with 9 samples.

How the data were processed

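The series holds 9 RNA libraries of mouse hippocampus, 3 per group, from sham mice, KA mice and KA mice given NBP. Total RNA was extracted with TRIzol, per the labels. The labels give each library its own title with a group and a replicate number and record no cage, batch or surgery date, so no such factor could be examined. The design gives replicate numbers no meaning across groups, and the fits reported do not pair them. Deviations from the group means were checked for pairing: in sham and KA+NBP the 3 same-number pairs correlated at 0.301, 0.332 and 0.126, all above 0.1, and pairs with different numbers at -0.310 to 0.192. KA+NBP replicate 3 correlated more with sham replicate 1 (0.192) than with its own number. Same-number pairs with a KA library ran from -0.0450 to 0.0447. A pairing of sham and KA+NBP libraries thus has its source in the values alone, and a fit with the replicate number as a block is given as an alternative.

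The deposited table gives for each of 18474 protein-coding genes and each library an estimated count, an FPKM and a TPM. Per the submitters' processing notes, Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 were used with the mouse genome GRCm39, and the role of each tool is not stated. Estimated counts as the authors deposited them are not whole numbers throughout: 5.65 to 6.61% of the values in a library carry a fraction, as reads shared by genes are divided between them. FPKM as deposited by the authors relates a count to transcript length and depth and was used only in an alternative fit. TPM as deposited by the authors was not used in any test. No raw read was used here.

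Totals were 16317066, 16109494 and 16182311 counts in sham, 16285829, 16149212 and 16374637 in KA and 16149028, 15699251 and 16303876 in KA+NBP. Between 16326 and 16886 genes had a count above 0 in a library, and the 10 most abundant genes held 2.83 to 3.31% of the counts. A bound of 3 counts for a gene without a count is 0.183 to 0.191 CPM in a library. Reads copied by PCR are not independent molecules, so intervals and bounds from counts are narrower than the true error. No pair of libraries was identical. Within groups the chi-square per degree of freedom of library pairs, where 1 is sampling noise alone, was 3.25 to 4.75 in sham, 7.26 to 15.3 in KA and 5.95 to 44.3 in KA+NBP, where the 2 pairs with replicate 2 gave 38.0 and 44.3. The sex-linked list was used as a check of the labels: the Y-linked genes Uty, Ddx3y, Eif2s3y and Kdm5d were present in all 9 libraries, Uty at 17.9 to 22.1 CPM, and 0 of the 4 were called in each comparison. As these genes were present in all 9 libraries, the check could not detect labels exchanged among them.

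Counts were rounded and fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14752. Normalization factors by TMM ran from 0.975 to 1.04. All 9 libraries entered 1 model with a mean per group, the common dispersion was 0.021, and each of the 3 comparisons was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes and an adjusted p threshold of 0.05. Log2 CPM, used for list tests, principal components and positions, took a prior count of 2. The log2 fold changes of genes come from the edgeR fit and did not use that prior count. The SE of a log2 fold change is its absolute value divided by the square root of F. A gene counts as not overlapping when every library of a group lies above every library of the other, which chance gives in 10% of genes with 3 and 3 libraries.

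Gene lists were written from general knowledge before the data were examined, as were the 3 comparisons, the tests and the first set of alternatives. Of 851 genes in 45 lists 822 were in the table. Some genes are on several lists, so the lists are not independent of each other. The 43 lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated as an alternative, and with fry. The adjusted p of a list is over the 43 lists of a comparison. The list of mitochondrially encoded genes had 13 members and 0 of them in the table, and the sex-linked list served as a check only. Besides the adjustment over all genes, members were adjusted over their list alone.

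Named genes follow a rule set before the values were seen. They are the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean is at least 1 CPM, or the 5 smallest p where fewer than 5 genes pass in a direction. A preset panel of 14 genes and up to 4 members with the smallest p of each list discussed are named as well. Predicted genes were passed over, except Gm2423. That gene and Phyhd1, which is not a predicted gene, are named outside the rule because they are the only genes called in a setting. A fold is given as a bound or with a counting interval where a group holds at most 3 counts in total.

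A position on the sham to KA axis is a weighted mean over the genes of a set called in KA against sham. Each gene is scaled so that the sham mean is 0 and the KA mean 100. Its weight is the square of its KA minus sham difference in log2 CPM, so genes with the largest change count most. Sham and KA libraries are placed without themselves. The overlap of 2 comparisons with shared libraries was compared with 100 simulations in which no gene changes. The pipeline was tested on simulated data made from these libraries. Apart from the changed genes, each gene had 1 mean and 1 spread in all groups, with no shifted library such as KA+NBP replicate 2. The shares recovered and called thus hold for such data and not for groups of unequal spread. In KA against sham (14627 genes) it recovered 40, 70, 92 and 94% of genes changed 1.5, 2, 4 and 8-fold, and 9.20% of its calls were unchanged genes. In KA+NBP against KA (14615 genes) the shares were 34, 71.4, 85.7 and 92% with 7.28% of calls unchanged, and in KA+NBP against sham (14614 genes) 36, 68.8, 90 and 92% with 7.19%. A list of 34 genes changed 1.5-fold was recovered in each comparison, with 0 unchanged lists called. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often unchanged lists are called where genes vary together.

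Alternatives were DESeq2 size factors in place of TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, limma on log2(FPKM + 1) for the 13408 genes with at least 1 FPKM in 3 libraries, only the 6 libraries compared, the replicate number as a block, and each library left out in turn. Leaving KA+NBP replicate 2 out of the fit for KA against sham was added after seeing the data. A change of pseudocount had been foreseen for a table with FPKM only and was not used here. GC content and names of genes came from a GRCm38 annotation, while positions are those of the deposited table. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.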

Results

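Hippocampal RNA from wild-type mice was sequenced in 3 groups of 3 libraries, named here sham, KA and KA+NBP, 30 days into treatment. KA is read here as kainic acid, a glutamate receptor agonist used to evoke seizures in mice, and NBP as the butylphthalide of the series title. The series design describes random allocation and 3 separate mice per group, so each library stands for 1 mouse. Library totals ran from 15699251 to 16374637 estimated counts over 18474 protein-coding genes, of which 14752 carried enough counts to be tested. At this depth a count of 0 in a library allows a level of up to 0.183 to 0.191 CPM (counts scaled to a common library total), and such floors and all counting intervals cover counting error only. Values below are CPM as mean ± SD with n = 3, and log2 fold changes carry a standard error (SE). Positions are gene spans on GRCm39, as the deposited table gives them, and each value covers the whole gene.

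The 9 libraries did not separate cleanly by group. The first principal component of log2 CPM held 72.2% of the variance. On an axis drawn over the genes that differed between KA and sham, with the sham mean at 0 and the KA mean at 100, the sham libraries lay at -5.59, 7.08 and 2.30 and the KA libraries at 93.2, 93.6 and 108. KA+NBP replicates 1 and 3 lay at -4.34 and -4.00, and KA+NBP replicate 2 at 58.1. Because of that spread, totals of genes and lists are also given without KA+NBP replicate 2, an alternative chosen after seeing the data where KA is compared with sham. For lists that passed, the count of members called in the direction of the list is given with a library left out where that moves it over 1.5 times.

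**Figure D1:**
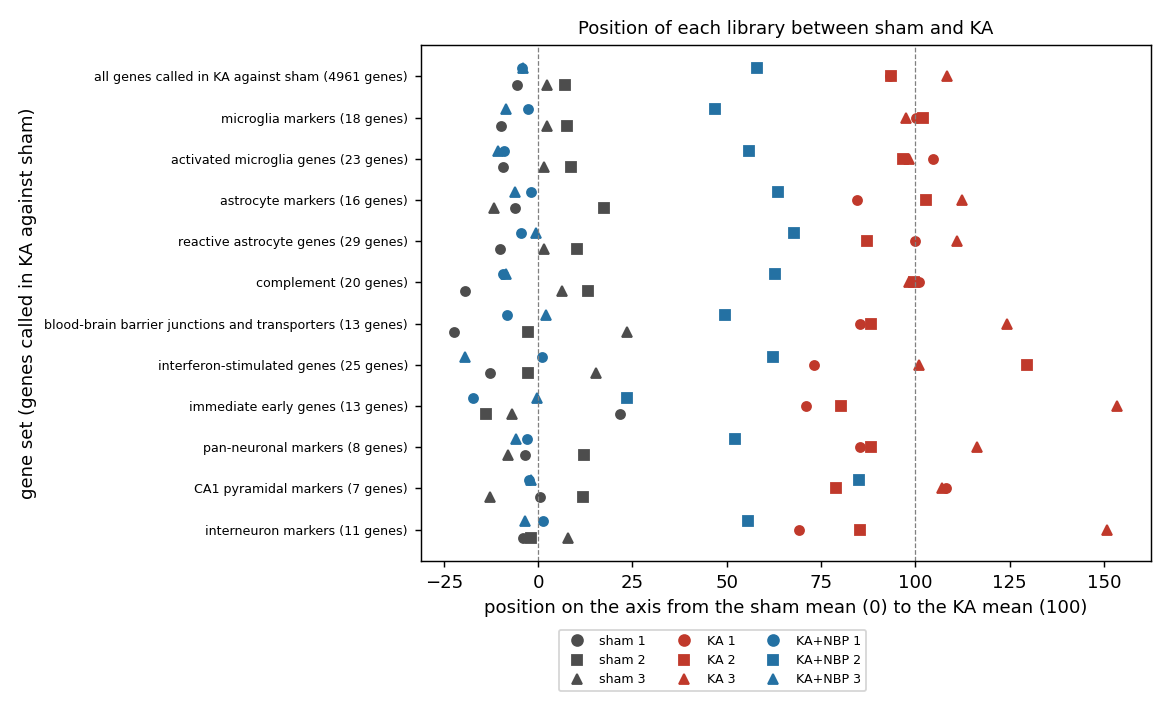
Position of each of the 9 libraries (points, colour for group, shape for replicate) on the axis from the sham mean (0) to the KA mean (100), for all genes that differed between KA and sham and for 11 gene lists. KA+NBP replicates 1 and 3 lie at -4.34 and -4.00 over all such genes and KA+NBP replicate 2 at 58.1.

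KA was compared with sham to ask what KA treatment had changed in the hippocampus by day 30. Of 34 complement genes 18 rose: C1qa, a chain of the protein that starts the classical complement pathway, stood at 339 ± 5.17 CPM in KA and 40.3 ± 7.80 in sham (log2 fold change 3.07, SE 0.42). Gfap, the intermediate filament of astrocytes, rose from 345 ± 39.9 to 4862 ± 691 CPM (3.82, SE 0.74), and Cd68, a lysosomal protein of microglia and macrophages, from 6.62 ± 0.241 to 80.2 ± 2.13 (3.60, SE 0.47). Bdnf, a neurotrophin induced by activity, rose from 37.1 ± 0.412 to 295 ± 90.2 CPM (2.99, SE 0.47). The neuronal splicing factor gene Rbfox3 fell by 0.75 (SE 0.11) on the log2 scale.

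In all, 4961 of 14752 genes differed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 2802 higher and 2159 lower in KA. Of these, 1267 were at least 2-fold higher and 216 at least 2-fold lower. The libraries of the 2 groups did not overlap for 8304 genes (56.3%), where chance gives 10%. The count was 6700 without KA+NBP replicate 2, 2721 without sham replicate 1 and 2762 without sham replicate 3. Cst7, an inhibitor of lysosomal cysteine proteases and the gene with the largest rise, went from 0.167 ± 0.0959 to 71.0 ± 6.61 CPM (8.67, SE 1.25). Other large rises were those of Tgm1, an epidermal-type transglutaminase (7.59, SE 1.28), and of the peptide hormone genes Trh (6.58, SE 0.98) and Cartpt (6.56, SE 1.07). Low counts in sham limit other folds: Cd5l and Ccl4 had no count in sham and were at least 21.7-fold and at least 20.7-fold higher in KA, against a floor of 3 counts over the group. Timp1, an inhibitor of matrix metalloproteinases, had 2 counts over the 3 sham libraries and 251 over KA, a ratio of 122 (95% counting interval 33.4 to 1012). Glycam1 had 1 and 131, a ratio of 127 (22.4 to 5065). Among the largest falls were Lct, the lactase gene (-3.09, SE 0.50), Iyd, which encodes iodotyrosine deiodinase (-3.30, SE 0.44), Plk5 (-2.84, SE 0.46) and Ccbe1 (-2.67, SE 0.35). Cldn22 had 83 counts in sham and 3 in KA, a ratio of 28.5 (9.41 to 141). Pla2g2f, a secreted phospholipase gene, fell by 3.09 (SE 0.58). Tdo2 (-2.98, SE 0.84) was no longer past the threshold without sham replicate 1 (adjusted p = 0.0678), sham replicate 3 (adjusted p = 0.0656), KA replicate 2 (adjusted p = 0.0776) or KA replicate 3 (adjusted p = 0.0775). Rtl3 (-2.78, SE 0.74) was lost without sham replicate 3 (adjusted p = 0.0634) or any 1 of the KA libraries (adjusted p = 0.0515 to 0.0683).

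Of the 34 complement genes tested, 18 rose and 2 fell (20 and 2 adjusted over the list alone), with a median log2 fold change of 1.34. Besides C1qa (Gene ID 12259, chromosome 4, 136623227 to 136626155), the members with the smallest p were Itgam, a chain of complement receptor 3 (1.67, SE 0.16), and the other C1q chains C1qb (2.93, SE 0.38) and C1qc (2.78, SE 0.40). C3, the component on which the complement pathways converge (Gene ID 12266, chromosome 17, 57510967 to 57535136), stood at 125 ± 34.1 and 4.17 ± 3.55 CPM (4.90, SE 1.27, edgeR adjusted p = 0.0182). That call was lost without sham replicate 1 (adjusted p = 0.0743) or sham replicate 3 (adjusted p = 0.0745). C4b (Gene ID 12268, chromosome 17, 34947249 to 34962876) rose from 69.2 ± 6.28 to 651 ± 8.50 CPM (3.23, SE 0.69), though it shares reads with a near-identical neighbour and its level is uncertain. Serping1, the C1 inhibitor gene, rose by 2.57 (SE 0.58). The list as a whole passed limma's camera at a preset correlation (adjusted p = 2.02e-04), and had adjusted p = 0.492 with an estimated correlation. Microglia markers rose with it, 18 of 19, and astrocyte markers, 16 of 18.

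Some genes of the blood-brain barrier rose. Of 27 junction and transporter genes, 12 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.43 and camera adjusted p = 0.00549, or adjusted p = 0.528 with an estimated correlation. F11r, which encodes junctional adhesion molecule A, rose by 1.43 (SE 0.22), Cav1, the caveolin of endothelial caveolae, by 1.66 (SE 0.34) and the lipoprotein receptor gene Lrp1 by 0.34 (SE 0.07). Cldn5, the main claudin of brain endothelium (Gene ID 12741, chromosome 16, 18595597 to 18597012), stood at 33.2 ± 2.81 CPM in KA and 21.5 ± 4.03 in sham (0.62, SE 0.19, edgeR adjusted p = 0.0336). Leaving out any 1 of the sham or KA libraries ended the Cldn5 call (adjusted p = 0.0527 to 0.114). The number of risen genes in this list was 4 and 5 without sham replicates 1 and 2, and 7, 7 and 5 without KA replicates 1, 2 and 3. The occludin gene Ocln (-0.04, SE 0.09, adjusted p = 0.783) and the zonula occludens gene Tjp1 (0.24, SE 0.12, adjusted p = 0.159) did not pass. Tjp1 passed without KA+NBP replicate 2 (adjusted p = 0.0127) and with the 6 sham and KA libraries fitted alone (adjusted p = 0.0208).

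Some markers of the vessel wall rose as well. Among 18 endothelial markers 9 rose and none fell (12 and 0 adjusted over the list alone), with Ly6a at 0.89 (SE 0.20) and Pecam1 at 0.74 (SE 0.16), and the list passed camera (adjusted p = 3.25e-04, adjusted p = 0.492 with an estimated correlation). Among 13 mural markers 11 rose (11 over the list alone), including the pericyte receptor gene Pdgfrb (0.70, SE 0.13) and the smooth muscle myosin gene Myh11 (0.93, SE 0.17), with camera adjusted p = 1.76e-04 and adjusted p = 0.492 with an estimated correlation. Of 15 fibroblast and meningeal markers 5 rose (11 over the list alone), including Serpinf1 (3.10, SE 0.49) and Igfbp2 (2.41, SE 0.43), with camera adjusted p = 8.03e-04 and adjusted p = 0.528 with an estimated correlation. Of 20 matrix remodelling genes 12 rose and 2 fell (12 and 2 over the list alone), including fibronectin, Fn1 (1.03, SE 0.14), and osteopontin, Spp1 (4.13, SE 0.64), with camera adjusted p = 0.00446 and adjusted p = 0.492 with an estimated correlation. Risen endothelial markers numbered 2 without sham replicate 1 or 2, 5 without KA replicate 2 and 3 without KA replicate 3, and mural markers 6 without sham replicate 1 or 2 and 7 without KA replicate 1 or 2. Fibroblast and meningeal markers numbered 13 without KA+NBP replicate 2, 3 without sham replicate 3 and 2 without sham replicate 1, sham replicate 2, KA replicate 1 or KA replicate 2. Glial lists rose beside all of these, activated microglia genes in 23 of 25 cases. Some genes are shared: Spp1 is also an activated microglia gene, Igfbp2 a choroid plexus marker and Cspg4 a mural and precursor marker. The lists are thus not separate evidence.

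Most microglial genes rose. Of 19 microglia markers 18 rose and none fell (18 and 0 adjusted over the list alone), with a median of 1.71, and of 25 activated microglia genes 23 rose (23 over the list alone), with a median of 3.27. Fcrls, an Fc receptor-like gene of resident microglia, rose by 2.80 (SE 0.18), Olfml3 by 2.25 (SE 0.21), the protease gene Ctsb by 1.27 (SE 0.10) and the chemokine gene Ccl6 by 4.46 (SE 0.34). Setting Ccl4 at its bound left the median of the activated list at 3.27. Astrocyte markers rose in 16 of 18 cases (16 over the list alone), including Acsbg1 (0.93, SE 0.09) and Aldh1l1 (0.88, SE 0.10). Reactive astrocyte genes rose in 29 of 35 (32, with 1 lower, over the list alone), among them the protease inhibitor gene Serpina3n at 3.79 (SE 0.51), which belongs to a family of near-identical copies, and Fbln5 at 3.12 (SE 0.43). Oligodendrocyte precursor markers rose in 8 of 11 (9 over the list alone), including Neu4 (0.86, SE 0.12), and in 5 without sham replicate 1 or sham replicate 3. In camera the adjusted p was 3.59e-10 for microglia, 5.29e-11 for activated microglia, 9.27e-07 for astrocyte, 1.68e-09 for reactive astrocyte and 4.65e-04 for precursor lists, and each of the 5 had adjusted p = 0.492 with an estimated correlation. The 19 oligodendrocyte and myelin genes did not pass (2 higher, 0 over the list alone, median 0.24, camera adjusted p = 0.16), though the list passed without sham replicate 2 (adjusted p = 0.0149) or KA replicate 3 (adjusted p = 0.0490).

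Some neuronal markers fell. Of 16 pan-neuronal markers 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.27, among them Rbfox1 (-0.66, SE 0.10) and Celf4 (-0.50, SE 0.09), both RNA-binding proteins. The list passed camera (adjusted p = 0.00327, adjusted p = 0.533 with an estimated correlation) but not without KA replicate 1 (adjusted p = 0.0522). Of 10 CA1 pyramidal markers 6 fell and 1 rose (7 and 1 over the list alone), including the transcription factor gene Pou3f1 (-1.50, SE 0.23) and Lefty1 (-1.96, SE 0.39), with camera adjusted p = 0.0158 and adjusted p = 0.496 with an estimated correlation. Of 20 interneuron markers 9 fell and 2 rose (12 and 3 over the list alone), including the neuregulin receptor gene Erbb4 (-1.05, SE 0.15) and the vesicular GABA transporter gene Slc32a1 (-0.62, SE 0.12), with camera adjusted p = 0.0169 and adjusted p = 0.492 with an estimated correlation. Fallen markers numbered 11 without KA+NBP replicate 2 in the pan-neuronal list, 3 without KA replicate 3 or any 1 of the sham libraries in the CA1 list, and 5 without sham replicate 1 or KA replicate 3 in the interneuron list. Glial markers rose in the same libraries, microglia in 18 of 19 cases. The lists for dentate granule cells (7 of 15 lower, 3 higher, the same over the list alone, camera adjusted p = 0.16) and for CA3 and CA2 (6 of 16 lower, 4 higher, 8 and 4 over the list alone, camera adjusted p = 0.0558) did not pass. The dentate list passed without KA replicate 1 (adjusted p = 0.0456), and the CA3 and CA2 list without sham replicate 1 (adjusted p = 0.0428), sham replicate 3 (adjusted p = 0.0458), KA replicate 3 (adjusted p = 0.0267) or KA+NBP replicate 2 (adjusted p = 0.0324). Within them the granule cell gene Stxbp6 fell by 0.78 (SE 0.09) and the CA3 gene Cpne4 by 1.59 (SE 0.22), while Coch rose by 2.75 (SE 0.46).

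Some genes of excitability and synapses fell in the same comparison. Of 32 voltage-gated channel genes 19 fell and 2 rose (19 and 2 adjusted over the list alone), among them the sodium channel genes Scn3a (-0.66, SE 0.07) and Scn4b (-1.66, SE 0.19) and the calcium channel gene Cacna1e (-1.12, SE 0.12), with camera adjusted p = 1.65e-04 and adjusted p = 0.517 with an estimated correlation. Of 22 glutamate receptor genes 12 fell and 3 rose (14 and 5 over the list alone), including the metabotropic receptor gene Grm5 (-0.81, SE 0.09) and the AMPA receptor gene Gria2 (-0.60, SE 0.09), with camera adjusted p = 8.03e-04 and adjusted p = 0.492 with an estimated correlation. Of 29 synaptic genes 12 fell and 1 rose (12 and 1 over the list alone), including Pclo (-0.72, SE 0.11) and Camk2a, the kinase of synaptic plasticity (-0.91, SE 0.18), with camera adjusted p = 2.04e-04 and adjusted p = 0.552 with an estimated correlation. In contrast, 13 of 26 immediate early genes rose and none fell (13 and 0 over the list alone), including Fosl2 (1.81, SE 0.23) and Fosb (1.73, SE 0.30), with camera adjusted p = 0.00111 and adjusted p = 0.517 with an estimated correlation. Of 25 activity-regulated neuropeptide and growth factor genes 16 rose and 1 fell (16 and 1 over the list alone), with Vgf at 1.70 (SE 0.23), Scg2 at 2.53 (SE 0.37) and the falling Nptx1 at -0.89 (SE 0.14), and camera gave adjusted p = 2.89e-04, or adjusted p = 0.492 with an estimated correlation. Fallen channel genes numbered 9 without sham replicate 1 or sham replicate 3 and 12 without KA replicate 3, and risen immediate early genes 6 without sham replicate 2 or sham replicate 3 and 7 without KA replicate 3. Npy, a peptide of interneurons, rose from 23.8 ± 0.724 to 109 ± 38.9 CPM (2.19, SE 0.45). Pan-neuronal markers fell in 7 of 16 cases beside these lists.

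Many immune genes rose. All 25 interferon-stimulated genes rose (25 adjusted over the list alone), including the transcription factor gene Irf7 (3.63, SE 0.54) and the antiviral sensor gene Oas1a (4.07, SE 0.61), with camera adjusted p = 2.67e-09 and adjusted p = 0.492 with an estimated correlation. Of 26 cytokine, chemokine and NF-kB target genes 18 rose (21 over the list alone), including Tgfb1 (1.86, SE 0.27) and the receptor gene Tgfbr2 (2.15, SE 0.34), with camera adjusted p = 4.43e-07 and adjusted p = 0.492 with an estimated correlation, and a median of 1.68 with or without Ccl4 at its bound. Of 19 antigen presentation genes 13 rose (13 over the list alone), including the peptide loading gene Tapbp (1.16, SE 0.19) and H2-DMb1 (2.30, SE 0.51), whose family shares reads between copies, with camera adjusted p = 1.31e-04 and adjusted p = 0.528 with an estimated correlation. Microglia markers rose in 18 of 19 cases beside them, while none of the 7 infiltrating leukocyte markers passed (0 over the list alone, median 2.26, camera adjusted p = 0.0969). That list passed without sham replicate 2 (adjusted p = 0.0204), sham replicate 3 (adjusted p = 0.0370), KA replicate 2 (adjusted p = 0.0453), KA replicate 3 (adjusted p = 0.0267) or KA+NBP replicate 2 (adjusted p = 0.00560). Risen interferon-stimulated genes numbered 15 and 16 without sham replicates 1 and 2, and antigen presentation genes 4, 5 and 7 without sham replicates 1, 2 and 3 and 7 without KA replicate 2. Leaving out KA+NBP replicate 2 brought 6 leukocyte markers past the threshold.

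Across the 43 lists tested, 27 passed camera at the preset correlation (21 higher, 6 lower; 29 without KA+NBP replicate 2), 25 passed limma's fry, which asks whether a list moves on balance in 1 direction, and 0 passed camera with an estimated correlation, where the smallest adjusted p was 0.492.

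**Figure D2:**
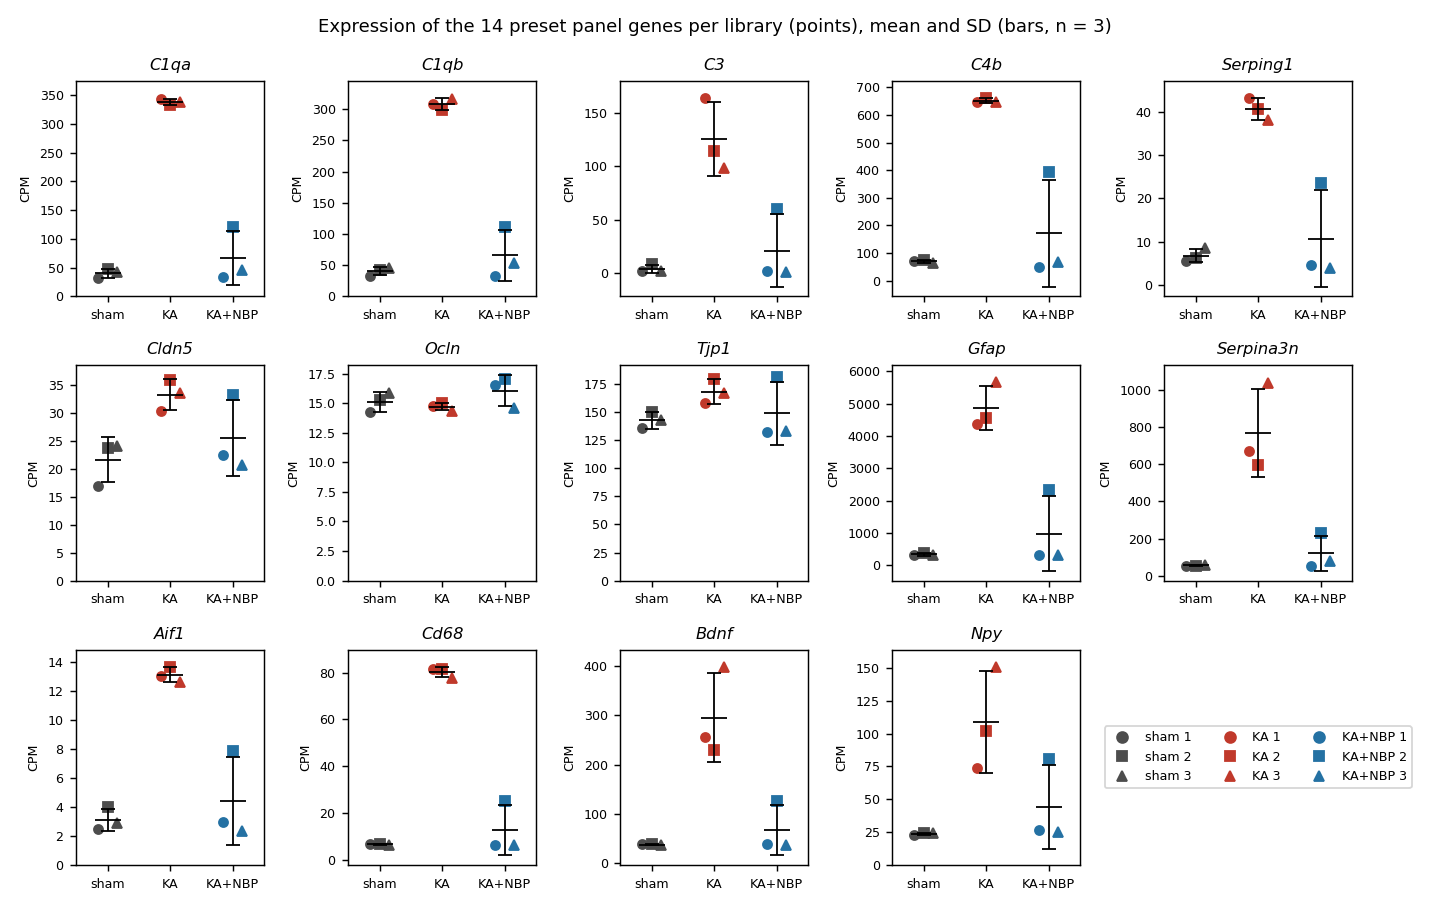
Expression (CPM, linear axes) of the 14 genes of the preset panel in each of the 9 libraries (points), with mean and SD per group (bars, n = 3). C1qa stood at 40.3 ± 7.80 in sham, 339 ± 5.17 in KA and 66.7 ± 47.8 in KA+NBP, where replicate 2 is the high library.

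KA+NBP was compared with KA to ask what butylphthalide had changed in KA-treated mice. Some complement genes were lower, 12 of 34: C1qa stood at 66.7 ± 47.8 CPM in KA+NBP and 339 ± 5.17 in KA (log2 fold change -2.34, SE 0.41), and C1qb at 65.7 ± 41.0 and 308 ± 9.09 (-2.23, SE 0.36). Cd68 fell to 12.5 ± 10.7 CPM (-2.67, SE 0.44) and Serpina3n from 769 ± 236 to 120.5 ± 95.5 (-2.67, SE 0.48). Rbfox3 rose by 0.63 (SE 0.11). The SD of the KA+NBP group reflects 1 library: C1qa was at 33.4, 121 and 45.2 CPM in KA+NBP replicates 1, 2 and 3.

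By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3355 of 14752 genes differed, 1480 higher and 1875 lower in KA+NBP, of which 139 were at least 2-fold higher and 791 at least 2-fold lower. Libraries of the 2 groups did not overlap for 5396 genes (36.6%), where chance gives 10%. The count was 6355 without KA+NBP replicate 2, 1295 without KA+NBP replicate 1, 1510 without KA+NBP replicate 3, and 2053, 2067 and 1741 without KA replicates 1, 2 and 3. With only the 6 libraries compared in the fit it was 1065. The count of 3355 rests on a spread shared with sham. Sham library pairs varied less (chi-square per degree of freedom 3.25 to 4.75) than KA+NBP pairs (5.95 to 44.3). The falls were led by genes that had risen in KA: Cst7 (-4.68, SE 0.85), Trh (-4.60, SE 0.82), Ccn5 (-4.46, SE 0.88), Cartpt (-4.31, SE 0.89) and Ccl6 (-4.29, SE 0.34). Cartpt was no longer past the threshold with the 6 libraries fitted alone (adjusted p = 0.0550). It was 1 of 53 genes, among those followed singly in each alternative, that lost their call in that fit, with 135 unchanged. Atp6v0d2, a proton pump subunit, and Cd5l had no count in KA+NBP and were at least 22.3-fold and at least 21.7-fold lower, against 3 counts over the group. Rises included Lct (2.80, SE 0.49), Plk5 (2.59, SE 0.46) and Iyd (2.59, SE 0.45), and Cldn22 went from 3 counts to 87, a ratio of 29.9 (95% counting interval 9.89 to 148). Sp8, a transcription factor gene (2.93, SE 0.76), was lost without KA replicate 2 (adjusted p = 0.0810) or KA replicate 3 (adjusted p = 0.0864), and Pla2g2f (2.70, SE 0.59) without KA replicate 3 (adjusted p = 0.0516). Tnfsf11 (-4.20, SE 0.96), which encodes the cytokine RANKL, was lost without KA replicate 3 (adjusted p = 0.0562), KA+NBP replicate 1 (adjusted p = 0.0605) or KA+NBP replicate 3 (adjusted p = 0.0540).

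The globin genes Hbb-bs (4.72, SE 1.39) and Hbb-bt (4.36, SE 1.31), which share reads, were called from KA+NBP replicate 1, at 78.4 and 15.3 CPM against 2.20 and 0.565 in replicate 3. Both calls were lost without that library (adjusted p = 0.175 and adjusted p = 0.197) or without any 1 KA library (adjusted p = 0.108 to 0.110 and adjusted p = 0.0843 to 0.119).

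Of the 34 complement genes 12 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -1.10 and camera adjusted p = 1.91e-04, or adjusted p = 0.492 with an estimated correlation. With KA+NBP replicate 2 left out 21 complement genes fell, against 6 without KA+NBP replicate 1 or 3 and 7 without KA replicate 2 or 3. Itgam fell by 1.41 (SE 0.15) and C1qc by 2.25 (SE 0.39). C3 (-2.56, SE 1.08, edgeR adjusted p = 0.117) and C4b (-1.93, SE 0.65, adjusted p = 0.0591) did not pass. Both passed without KA+NBP replicate 2 (adjusted p = 3.17e-05 and adjusted p = 3.90e-07) and by limma on log2(FPKM + 1) (adjusted p = 0.0193 and adjusted p = 0.0200). Serping1 (-1.91, SE 0.55, adjusted p = 0.0371) passed, but not without any 1 of the KA libraries, KA+NBP replicate 1 or KA+NBP replicate 3 (adjusted p = 0.0805 to 0.109). On the sham to KA axis for 20 complement genes KA+NBP replicate 2 lay at 62.9 and replicates 1 and 3 at -9.20 and -8.47. Microglia markers moved alongside, with replicate 2 at 46.9 and the other libraries at -2.78 and -8.45.

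Some barrier and vessel genes fell, in numbers that changed with single libraries. Of 27 junction and transporter genes 5 fell and none rose (5 and 0 adjusted over the list alone), with a median of -0.31 and camera adjusted p = 0.0106, or adjusted p = 0.512 with an estimated correlation. With KA+NBP replicate 2 left out 16 of them fell, and 2 without KA replicate 2 and 1 without KA replicate 3 or KA+NBP replicate 1. F11r fell by 1.25 (SE 0.22) and Cav1 by 1.44 (SE 0.34), the latter not past the threshold without KA replicate 3 (adjusted p = 0.0622) or KA+NBP replicate 1 (adjusted p = 0.0706). Cldn5 (-0.38, SE 0.19, adjusted p = 0.172), Ocln (0.13, SE 0.09, adjusted p = 0.349) and Tjp1 (-0.18, SE 0.12, adjusted p = 0.314) did not pass in edgeR's test, and without KA+NBP replicate 2 Cldn5 (adjusted p = 0.00713) and Tjp1 (adjusted p = 0.00367) did. Of 13 mural markers 8 fell (12 over the list alone), including the receptor gene Notch3 (-1.15, SE 0.23) and Myh11 (-0.81, SE 0.17), the latter lost without KA+NBP replicate 1 (adjusted p = 0.0525). Of 18 endothelial markers 5 fell (7 over the list alone). Their most significant members, Pecam1 (-0.61, SE 0.16) and Eng (-0.69, SE 0.19), kept their calls without KA+NBP replicate 2 alone, and lost them without any other single KA or KA+NBP library (adjusted p = 0.0503 to 0.104 and adjusted p = 0.0571 to 0.0913). Camera gave adjusted p = 3.87e-05 for mural and adjusted p = 3.00e-04 for endothelial markers, and each had adjusted p = 0.492 with an estimated correlation. Of 20 matrix genes 10 fell and 2 rose (12 and 2 over the list alone), including Timp2 (-0.59, SE 0.09) and Spp1 (-3.26, SE 0.60), with camera adjusted p = 0.00809 and adjusted p = 0.492 with an estimated correlation. Fallen endothelial markers numbered 15 without KA+NBP replicate 2, 1 without KA+NBP replicate 3 and 0 without KA+NBP replicate 1 or any 1 KA library. For mural markers the numbers were 13 without KA+NBP replicate 2, 2 without KA+NBP replicate 1 or 3 and 5 without KA replicate 1 or 2, and for matrix genes 4 without KA+NBP replicate 1 or 3, 5 without KA replicate 1 and 6 without KA replicate 3. KA+NBP replicate 2 lay at 49.6 for barrier genes, 53.3 for mural and 65.7 for endothelial markers.

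Many glial and immune genes fell. Microglia markers fell in 18 of 19 cases (18 adjusted over the list alone), including Fcrls (-2.29, SE 0.17) and Olfml3 (-1.72, SE 0.21), and activated microglia genes in 20 of 25 (23 over the list alone), including Ctsb (-1.10, SE 0.10) and the growth factor gene Csf1 (-0.99, SE 0.12). Astrocyte markers fell in 12 of 18 (13 over the list alone), including Acsbg1 (-0.74, SE 0.09), and reactive astrocyte genes in 21 of 35 (26, with 1 higher, over the list alone), including Fbln5 (-2.45, SE 0.41). Gfap stood at 983 ± 1159 CPM in KA+NBP (-2.31, SE 0.70, adjusted p = 0.0427), with 313, 2321 and 314 in replicates 1, 2 and 3. Gfap and Aif1, a calcium-binding protein of microglia (-1.57, SE 0.39, adjusted p = 0.0222), both lost their calls without any 1 of the KA libraries, KA+NBP replicate 1 or KA+NBP replicate 3 (adjusted p = 0.0792 to 0.108 and adjusted p = 0.0553 to 0.0804). Of 25 interferon-stimulated genes 17 fell (25 over the list alone), including Oas1a (-3.34, SE 0.58) and Irf7 (-2.62, SE 0.50). Of 26 cytokine genes 14 fell (19 over the list alone), including Tgfb1 (-1.86, SE 0.27) and Tnfrsf1a (-1.67, SE 0.33). Camera gave adjusted p = 2.49e-11 for microglia, 5.46e-12 for activated microglia, 1.78e-05 for astrocyte, 1.77e-08 for reactive astrocyte, 6.70e-09 for interferon and 1.55e-06 for cytokine lists, and each had adjusted p = 0.492 with an estimated correlation. Single libraries moved several of these numbers. Without KA+NBP replicate 2 the fallen genes were 22 for cytokines, 25 for interferon-stimulated and 30 for reactive astrocyte genes. Leaving out KA replicates 1, 2 and 3 and KA+NBP replicates 1 and 3 in turn gave 7, 4, 5, 4 and 5 astrocyte markers, 10, 14, 5, 7 and 6 reactive astrocyte genes, 16, 6, 9, 5 and 7 interferon-stimulated genes and 7, 7, 5, 4 and 8 cytokine genes. Replicate 2 of KA+NBP lay at 56.0 for activated microglia, 67.7 for reactive astrocyte and 62.2 for interferon-stimulated genes, where the other KA+NBP libraries lay between -19.4 and 0.964.

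Some neuronal genes rose. Of 32 voltage-gated channel genes 12 rose and 2 fell (17 and 2 adjusted over the list alone), including Scn3a (0.67, SE 0.07) and Cacna1e (1.05, SE 0.12), with camera adjusted p = 2.47e-04 and adjusted p = 0.512 with an estimated correlation. Of 22 glutamate receptor genes 9 rose and 1 fell (10 and 2 over the list alone), including Grm5 (0.73, SE 0.09) and the kainate receptor gene Grik2 (0.46, SE 0.07), with camera adjusted p = 9.75e-04 and adjusted p = 0.492 with an estimated correlation. Of 29 synaptic genes 9 rose and 1 fell (11 and 1 over the list alone), including Pclo (0.61, SE 0.11) and Nrxn3 (0.54, SE 0.11), with camera adjusted p = 0.00163 and adjusted p = 0.582 with an estimated correlation. Of 16 pan-neuronal markers 6 rose and 1 fell (7 and 1 over the list alone), including Rbfox1 (0.68, SE 0.10), with camera adjusted p = 0.00462, adjusted p = 0.512 with an estimated correlation and adjusted p = 0.0900 without KA replicate 1. Of 20 interneuron markers 7 rose (9, with 1 lower, over the list alone), including Slc32a1 (0.76, SE 0.12), with camera adjusted p = 0.0171, adjusted p = 0.492 with an estimated correlation and adjusted p = 0.0576 without KA replicate 1. Of 10 CA1 markers 4 rose and 1 fell (5 and 1 over the list alone), including Pou3f1 (1.24, SE 0.23), with camera adjusted p = 0.0347 and adjusted p = 0.512 with an estimated correlation. The CA1 call was lost without KA replicate 1 (adjusted p = 0.0828), KA replicate 3 (adjusted p = 0.0632) or KA+NBP replicate 1 (adjusted p = 0.0695). Risen genes without KA+NBP replicate 2 numbered 22 channel, 14 glutamate receptor, 18 synaptic, 10 pan-neuronal, 11 interneuron and 7 CA1 genes. Leaving out KA replicates 1, 2 and 3 and KA+NBP replicates 1 and 3 in turn gave 6, 6, 6, 4 and 5 channel genes, 4, 6, 2, 2 and 3 synaptic genes, 3, 4, 3, 3 and 3 pan-neuronal markers, 6, 5, 4, 4 and 5 interneuron markers and 1, 3, 1, 1 and 2 CA1 markers. KA+NBP replicate 2 lay at 85.2 for CA1, 52.2 for pan-neuronal and 55.6 for interneuron markers. For CA1 markers KA replicates 1, 2 and 3 lay at 108, 78.9 and 107, so KA+NBP replicate 2 was within the KA range there.

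Some activity-regulated genes fell. Of 26 immediate early genes 11 fell (17 adjusted over the list alone), including Fosl2 (-1.59, SE 0.23) and Fosb (-1.92, SE 0.30), with a median of -0.72, camera adjusted p = 2.57e-05 and adjusted p = 0.492 with an estimated correlation. Here KA+NBP replicate 2 lay lower on the axis, at 23.7. Of 25 neuropeptide and growth factor genes 11 fell and 1 rose (14 and 2 over the list alone), including Vgf (-1.37, SE 0.23) and Igf1 (-1.13, SE 0.16), with camera adjusted p = 9.75e-04 and adjusted p = 0.512 with an estimated correlation, and KA+NBP replicate 2 at 67.2. Fallen immediate early genes numbered 6 and 7 without KA+NBP replicates 1 and 3, and neuropeptide genes 6, 7 and 6 without KA+NBP replicate 1, KA+NBP replicate 3 and KA replicate 3. Bdnf fell from 295 ± 90.2 to 66.8 ± 51.8 CPM (-2.14, SE 0.45, adjusted p = 0.0129), a call lost with the 6 libraries fitted alone (adjusted p = 0.0564). Npy (-1.30, SE 0.43, adjusted p = 0.0568) passed by DESeq2 (adjusted p = 0.0448) and by limma on log2(FPKM + 1) (adjusted p = 0.0304) or without KA+NBP replicate 2 (adjusted p = 1.55e-04). In total 26 of 43 lists passed camera (6 higher, 20 lower; 28 without KA+NBP replicate 2), 20 passed fry and 0 passed camera with an estimated correlation, where the smallest adjusted p was 0.492.

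The changes of the 2 comparisons were set against each other. Of the 2802 genes higher in KA than sham, 1781 (63.6%) were called lower in KA+NBP than KA, where independent lists would share 356, and of the 2159 lower genes 1396 (64.7%) were called higher, where independent lists would share 217. No gene was called in the same direction in both. The sign was opposite for 4958 of the 4961 genes called in KA against sham (99.9%), and in the single KA+NBP libraries for 99.9%, 94.5% and 99.7%. Both comparisons use the same KA libraries, which by itself gives opposite signs. In 100 simulations of unchanged groups with shared libraries 76.8% (75.3 to 78.3) of the 4961 genes with the largest change had opposite signs, against 99.0% observed for such genes. Over all tested genes the covariance of the log2 fold changes was -0.446 and the simulated value -0.0329 (-0.0382 to -0.0288), a difference of -0.413. The correlation across genes, which are not independent replicates, was -0.964 and the simulated value -0.499. With 3 KA libraries no split leaves 2 libraries on each side, so part of the excess over independent lists may come from the shared libraries.

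**Figure D3:**
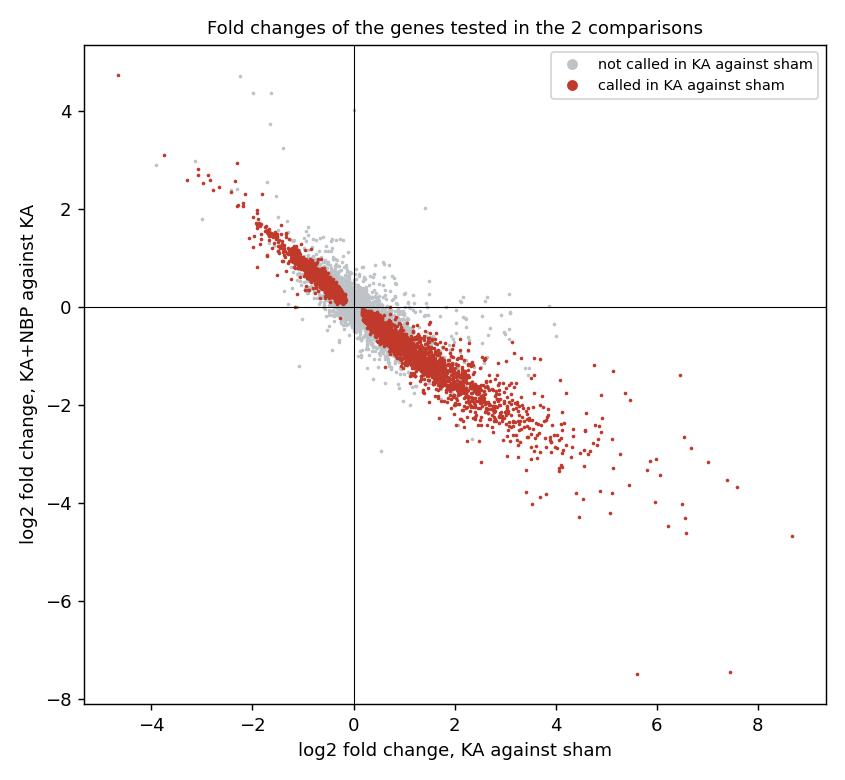
Log2 fold change of each of the 14752 tested genes in KA against sham (horizontal axis) and in KA+NBP against KA (vertical axis), with the genes called in KA against sham in red. Of the 4961 red genes 4958 have opposite signs, in 2 comparisons that share the KA libraries.

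KA+NBP was compared with sham to ask what still differed in KA-treated mice given butylphthalide. No gene passed edgeR's test. Serpina3n stood at 120.5 ± 95.5 CPM against 55.6 ± 2.12 in sham (1.12, SE 0.47), Gfap at 983 ± 1159 against 345 ± 39.9 (1.51, SE 0.68) and C3 at 21.2 ± 33.9 against 4.17 ± 3.55 (2.34, SE 1.25), with 60.3 CPM of C3 in KA+NBP replicate 2 and 2.42 and 0.753 in replicates 1 and 3. Bdnf was at 66.8 ± 51.8 and 37.1 ± 0.412 CPM (0.85, SE 0.45).

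The count of 0 by edgeR's quasi-likelihood test came with 248 genes at an unadjusted p under 0.05, where 737.6 would be expected by chance, and a smallest adjusted p of 1.00. limma on log2(FPKM + 1) also called 0 genes. DESeq2 called 1, the predicted gene Gm2423 (-0.50, adjusted p = 0.0469), and edgeR without KA+NBP replicate 1 called 1, Phyhd1 (1.01, adjusted p = 0.0475), both named after their values were seen. Without KA+NBP replicate 2 the count stayed at 0, with 463 at an unadjusted p under 0.05. Libraries of the 2 groups did not overlap for 939 genes (6.37%), where chance gives 10%. Numbers of genes below the chance value, here and for unadjusted p, do not show that the groups are alike. KA+NBP replicate 2 widened the spread of its group, so the count of 0 can miss real differences. The genes with the smallest p, none past the threshold, were higher for Rhod (2.07, SE 0.52), Treml2 (1.86, SE 0.49), the histone methyltransferase gene Ezh2 (0.64, SE 0.17), the glycosyltransferase gene B3gnt5 (1.21, SE 0.33) and Tmem129 (0.26, SE 0.07), and lower for Cwc25 (-0.30, SE 0.09), Mid1 (18.3 ± 1.55 against 36.6 ± 18.3 CPM), Fabp7 (-0.60, SE 0.18), Xxylt1 (-0.23, SE 0.07) and Leng9 (-0.47, SE 0.15).

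Gene lists differed at the preset correlation alone. Camera passed 15 of 43 lists, 11 higher and 4 lower in KA+NBP, but fry passed 0 and camera with an estimated correlation passed 0, with adjusted p = 0.778 with an estimated correlation for each of the 15. No member of any list was called, over all genes or adjusted over the list alone. The smallest adjusted p at the preset correlation, 3.95e-05, belonged to astrocyte markers (median 0.18), with Fgfr3 at 0.32 (SE 0.13), and to reactive astrocyte genes (median 0.82), with B3gnt5 at 1.21 (SE 0.33). Synaptic genes had a median of -0.07 (adjusted p = 0.00412), interferon-stimulated genes of 0.65 (adjusted p = 0.00412) and cytokine genes of 0.42 (adjusted p = 0.00412). KA+NBP replicate 2 set much of this: without it 18 lists passed, 5 higher and 13 lower, and 3 of them matched the 15 in list and direction. Activated microglia genes, with a median of 0.62 (adjusted p = 0.0121), had a median of -0.23 (adjusted p = 6.50e-05) without that library. Without it astrocyte (adjusted p = 0.555), reactive astrocyte (adjusted p = 0.129) and cytokine genes (adjusted p = 0.110) did not pass, interferon-stimulated genes passed downward (adjusted p = 0.0394) and synaptic genes upward (adjusted p = 0.00757). Without sham replicate 1 activated microglia (adjusted p = 0.116), synaptic (adjusted p = 0.0567), interferon-stimulated (adjusted p = 0.0567) and cytokine genes (adjusted p = 0.140) did not pass. The count of lists was 4 without sham replicate 1, 28 without KA+NBP replicate 1 and 30 without KA+NBP replicate 3. Complement (median 0.30, adjusted p = 0.116) and barrier genes (median 0.09, adjusted p = 0.169) did not pass, and complement passed downward without KA+NBP replicate 2 (median -0.14, adjusted p = 0.00827). Both passed upward without sham replicate 3 (adjusted p = 0.0104 and adjusted p = 0.0360), KA+NBP replicate 1 (adjusted p = 0.00403 and adjusted p = 0.0387) or KA+NBP replicate 3 (adjusted p = 0.0423 and adjusted p = 0.0140).

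**Figure D4:**
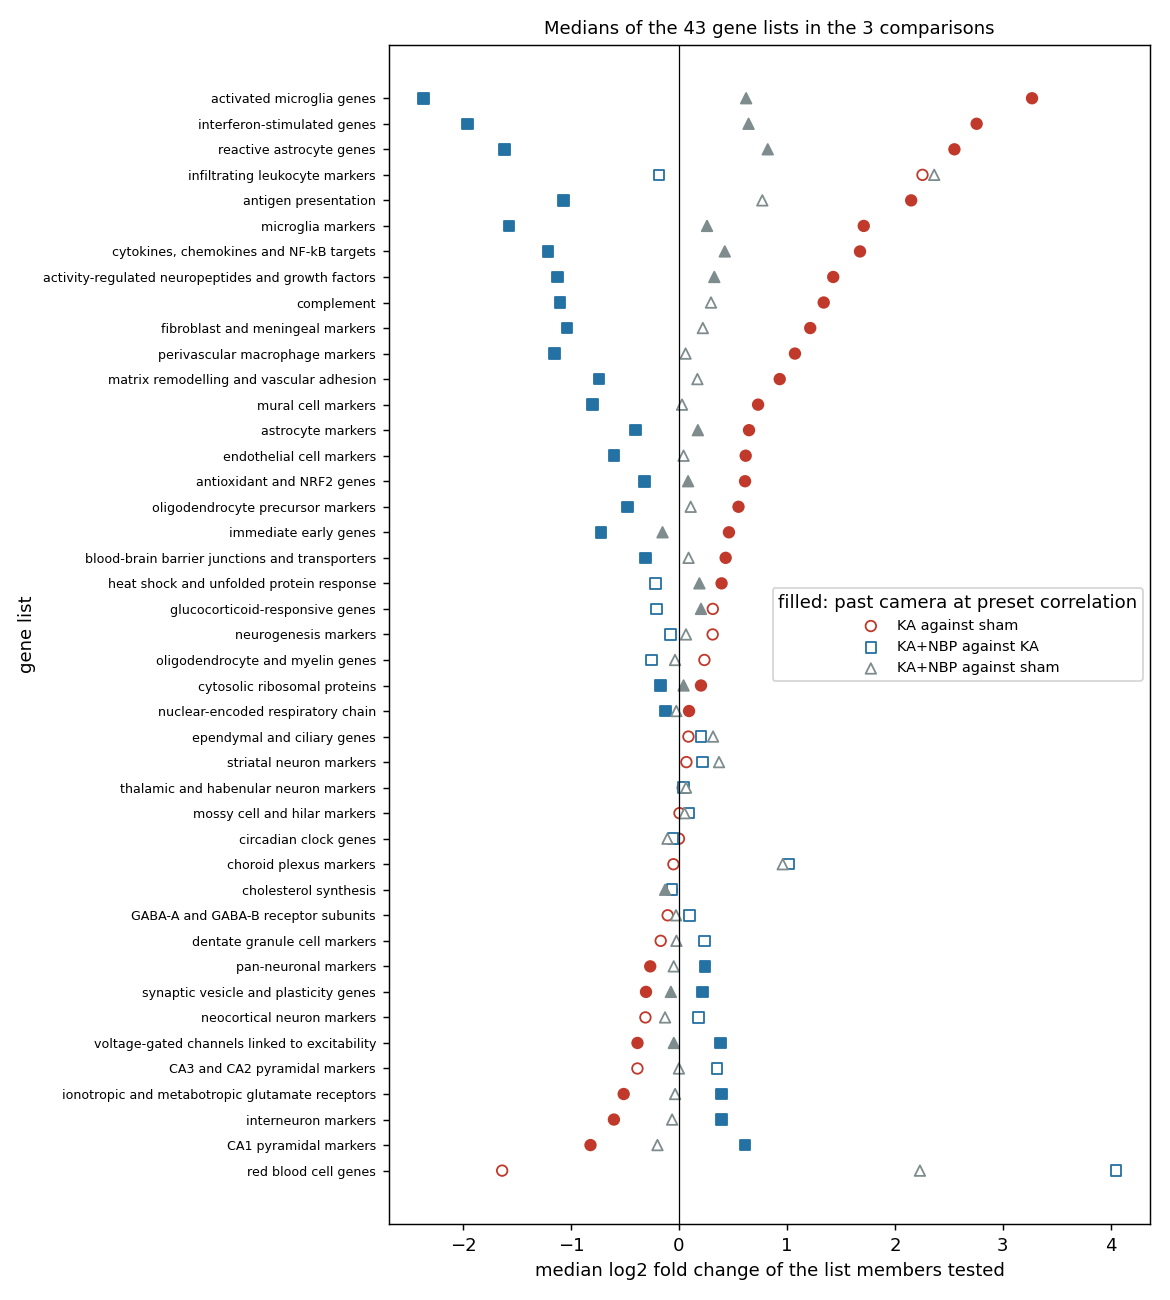
Median log2 fold change of the tested members of each of the 43 gene lists (lists on the vertical axis, log2 fold change on the horizontal axis) in the 3 comparisons (colour and shape), filled where the list passed camera at the preset correlation. Activated microglia genes have a median of 3.27 in KA against sham, -2.37 in KA+NBP against KA and 0.62 in KA+NBP against sham.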

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

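With other normalization, no filter or limma on log2(FPKM + 1) the numbers of genes stayed within 1.5 times those reported in all 3 comparisons. DESeq2 called 1 gene in KA+NBP against sham, where edgeR called 0, and gave 27 lists there in place of 15. With only the 6 libraries compared, KA+NBP against KA gave 1065 genes in place of 3355. Of the genes followed singly there, 53 lost their call and 135 were unchanged, and not each loss is named beside its gene. With the correlation between genes estimated, 0 lists passed in each comparison, and fry passed 0 lists in KA+NBP against sham. The pseudocount alternative was not run, as counts were at hand.

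Leave-one-out counts of genes ran from 2721 to 6700 in KA against sham, from 1295 to 6355 in KA+NBP against KA and from 0 to 1 in KA+NBP against sham. The number of lists in KA+NBP against sham ran from 4 to 30, and in the other comparisons from 26 to 30 each. With 2 libraries left in a group, part of such a change comes from the smaller number.

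Signs turned mainly without KA+NBP replicate 2, and the cause was not tested. Without it Ttr in KA+NBP against KA went from 4.02 to -3.44 (adjusted p = 2.71e-04), with leave-one-out values from -3.44 to 4.60. In KA+NBP against sham 28 lists turned direction without that library, 16 of them past the threshold in either fit. For these 16 the leave-one-out adjusted p ran from 0.00403 to 0.813 for complement, 0.00510 to 0.974 for mural, 6.50e-05 to 0.982 for fibroblast and meningeal, 1.24e-05 to 0.279 for microglia and 1.24e-05 to 0.116 for activated microglia genes. It ran from 3.94e-08 to 0.129 for reactive astrocyte, 0.0207 to 0.675 for pan-neuronal, 5.16e-07 to 0.576 for choroid plexus, 1.16e-04 to 0.912 for ependymal and 4.23e-04 to 0.140 for leukocyte genes. For voltage-gated channels the range was 7.58e-04 to 0.276, for synaptic genes 2.73e-05 to 0.0567, for cytokines 1.00e-04 to 0.140, for interferon-stimulated genes 1.20e-07 to 0.0567, for antigen presentation 4.85e-07 to 0.576 and for antioxidant genes 0.00368 to 0.384. Oligodendrocyte (8.25e-04 to 0.442) and glucocorticoid-responsive lists (3.19e-04 to 0.357) turned without KA+NBP replicate 3.

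With the replicate block the counts were 4784, 3189 and 0 genes and 29, 27 and 16 lists, and in KA+NBP against sham, the comparison whose same-number pairs correlated, 3 lists changed their call and no gene did. Of the genes followed singly, 3 gained a call in KA against sham. In KA+NBP against KA 10 gained and 6 lost theirs.

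Over all alternatives for single genes, KA against sham gave 2315 unchanged calls, 54 gained and 99 lost, and KA+NBP against KA gave 1953 unchanged, 64 gained, 231 lost and 1 turned in sign. For single lists the numbers were 576, 26 and 41 in KA against sham, 535, 25 and 40 in KA+NBP against KA, and 452, 67 and 61 in KA+NBP against sham, where 18 turned.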

Other observations

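Beyond the lists of the report, some genes of stress and metabolism rose between sham and KA. Antioxidant and NRF2 genes rose in 11 of 23 cases with 1 lower (12 and 1 adjusted over the list alone), including the metallothionein gene Mt2 (1.99, SE 0.25) and the heme oxygenase gene Hmox1 (1.61, SE 0.24), with camera adjusted p = 3.24e-04 and adjusted p = 0.492 with an estimated correlation. In KA+NBP against KA 10 fell (11 over the list alone), Mt2 by 1.54 (SE 0.25) and Hmox1 by 1.45 (SE 0.24), with camera adjusted p = 6.79e-04 and adjusted p = 0.492 with an estimated correlation. Of 21 heat shock and unfolded protein genes 10 rose in KA (11 over the list alone), including Hspb1 (3.06, SE 0.56) and Atf3 (2.89, SE 0.59), with camera adjusted p = 0.0119 and adjusted p = 0.552 with an estimated correlation. That list did not pass in KA+NBP against KA (3 lower, 1 higher, the same over the list alone, camera adjusted p = 0.0767), except without KA replicate 1 (adjusted p = 0.0143), KA replicate 2 (adjusted p = 0.0326) or KA+NBP replicate 3 (adjusted p = 0.0310). Of 37 ribosomal protein genes 15 rose in KA (16 over the list alone, Rplp0 by 0.44, SE 0.06, camera adjusted p = 2.02e-04, adjusted p = 0.528 with an estimated correlation) and 8 fell in KA+NBP against KA (8 over the list alone, Rplp0 by 0.39, SE 0.06, camera adjusted p = 8.16e-04, adjusted p = 0.512 with an estimated correlation). Of 30 respiratory chain genes 8 rose in KA (6 over the list alone, Sdhc by 0.36, SE 0.06, camera adjusted p = 0.0242, adjusted p = 0.552 with an estimated correlation), a list call lost without sham replicate 2 (adjusted p = 0.136) or KA replicate 3 (adjusted p = 0.0664). In KA+NBP against KA 7 fell (7 over the list alone, Ndufa2 by 0.35, SE 0.07, camera adjusted p = 0.00217, adjusted p = 0.512 with an estimated correlation), a call lost without KA+NBP replicate 2 (adjusted p = 0.0838). Risen heat shock genes numbered 4 without sham replicate 1, sham replicate 3 or KA replicate 3 and 5 without sham replicate 2, ribosomal genes 5 without sham replicate 1, sham replicate 3 or KA replicate 1 and 7 without sham replicate 2, and respiratory genes 4 without sham replicate 1 or 2 and 3 without sham replicate 3 or KA replicate 3. Fallen ribosomal genes in KA+NBP against KA numbered 19 without KA+NBP replicate 2, 3 without KA+NBP replicate 1 or 3, 4 without KA replicate 1 and 5 without KA replicate 3, and respiratory genes 4 without KA replicate 1 or KA+NBP replicate 1 and 3 without KA replicate 3 or KA+NBP replicate 3. Microglia markers rose in 18 of 19 cases in KA and fell in 18 of 19 in KA+NBP against KA beside all of these.

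Further lists of KA+NBP against KA completed the picture of glial, vascular and neuronal genes. Fibroblast and meningeal markers fell in 4 of 15 cases (4 over the list alone), including Igfbp2 (-2.01, SE 0.42) and Serpinf1 (-2.20, SE 0.46), with camera adjusted p = 8.16e-04 and adjusted p = 0.512 with an estimated correlation. With the 6 libraries fitted alone neither gene passed (adjusted p = 0.0507 and adjusted p = 0.0563). Oligodendrocyte precursor markers fell in 6 of 11 (7 over the list alone), including C1ql1 (-0.68, SE 0.13), with camera adjusted p = 0.00111 and adjusted p = 0.492 with an estimated correlation. Antigen presentation genes fell in 5 of 19 (6 over the list alone), including Tapbp (-1.07, SE 0.19), with camera adjusted p = 1.99e-04 and adjusted p = 0.512 with an estimated correlation. Without KA+NBP replicate 2 the fallen genes numbered 13 fibroblast and meningeal, 17 antigen presentation, 7 perivascular macrophage and 5 oligodendrocyte genes. Leaving out another library gave 2 fibroblast and meningeal markers (KA replicates 1 and 2, KA+NBP replicates 1 and 3), 1 antigen presentation gene (any other KA or KA+NBP library), 2 precursor markers (KA+NBP replicate 3) and 0 oligodendrocyte genes (any KA library or KA+NBP replicate 1).

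Perivascular macrophage markers had 1 of 7 past the threshold in each direction (1 over the list alone): Stab1, a scavenger receptor gene, rose 2.33-fold in KA and fell to 0.488 of the KA level in KA+NBP (edgeR adjusted p = 0.00428 and adjusted p = 0.0120). In KA against sham 4 of them rose without KA+NBP replicate 2. Their camera adjusted p was 0.0490 in KA against sham, lost without sham replicate 1 (adjusted p = 0.103), sham replicate 2 (adjusted p = 0.0877), KA replicate 1 (adjusted p = 0.0668) or KA replicate 2 (adjusted p = 0.0841), and 0.0133 in KA+NBP against KA, with adjusted p = 0.552 and adjusted p = 0.512 with an estimated correlation. Dentate granule markers (6 of 15 higher, 2 lower, 7 and 4 over the list alone, camera adjusted p = 0.0768) and CA3 and CA2 markers (6 of 16 higher, 1 lower, 9 and 4 over the list alone, camera adjusted p = 0.0532) did not pass, while Stxbp6 rose by 0.70 (SE 0.09), C1ql2 by 1.25 (SE 0.20), Cpne4 by 1.43 (SE 0.22) and Rgs14 by 0.89 (SE 0.17). The dentate list passed without KA replicate 1 (adjusted p = 0.0181) or KA+NBP replicate 1 (adjusted p = 0.0346), and the CA3 and CA2 list without KA replicate 3 (adjusted p = 0.0211), KA+NBP replicate 2 (adjusted p = 0.0438) or KA+NBP replicate 3 (adjusted p = 0.0234). Oligodendrocyte and myelin genes did not pass (1 lower, 0 over the list alone, camera adjusted p = 0.0610), except without KA replicate 3 (adjusted p = 0.0149), KA+NBP replicate 1 (adjusted p = 0.0346) or KA+NBP replicate 2 (adjusted p = 0.0108).

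The remaining lists did not pass between KA and sham or between KA+NBP and KA, and some single members did. GABA receptor subunits had camera adjusted p = 0.345 and adjusted p = 0.269, with Gabrg3 at -0.60 (SE 0.08) and 0.57 (SE 0.08). Circadian genes had adjusted p = 0.556 and adjusted p = 0.979, with Npas2 at 1.14 (SE 0.13) and -0.98 (SE 0.13). Neurogenesis markers had adjusted p = 0.679 and adjusted p = 0.827, with Dcx, a protein of young neurons, at -0.71 (SE 0.14) and 0.77 (SE 0.14), and in the latter comparison a median of -0.08, a mean of 0.11 and a test pointing up. Cholesterol synthesis had adjusted p = 0.417 and adjusted p = 0.683 and passed without KA replicate 3 in the first (adjusted p = 8.64e-04) and without KA replicate 1 in the second (adjusted p = 0.0215). Glucocorticoid-responsive genes had adjusted p = 0.0658 and adjusted p = 0.251, with Mt1 at 1.74 (SE 0.21) and -1.14 (SE 0.21). They passed without sham replicate 1 (adjusted p = 0.0470), sham replicate 3 (adjusted p = 0.0407) or KA replicate 2 (adjusted p = 0.0209) in the first comparison and without KA+NBP replicate 3 (adjusted p = 0.00217) in the second. Mossy cell (adjusted p = 0.983 and adjusted p = 0.827), thalamic (adjusted p = 0.679 and adjusted p = 0.827), neocortical (adjusted p = 0.289 and adjusted p = 0.348) and ependymal lists (adjusted p = 0.561 and adjusted p = 0.948) did not pass. Mossy cell genes in KA against sham had a mean of 0.05 and a test pointing down, and ependymal genes in KA+NBP against KA a median of 0.20 and a test pointing down. Striatal markers, with Rasd2 at -1.29 (SE 0.14) and 1.08 (SE 0.14), had adjusted p = 0.931, where a median of 0.07 and a mean of 0.37 met a test pointing down, and adjusted p = 0.373, with adjusted p = 0.0420 without KA+NBP replicate 1.

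Some genes of other tissues stood out in single libraries. The choroid plexus marker Ttr was at 553 CPM in KA+NBP replicate 2 and lower in the other KA+NBP libraries (0.691 in replicate 3) than in any sham or KA library (7.05 to 17.2). The choroid plexus list did not pass in KA against sham (median -0.05, mean 0.14, test pointing down, camera adjusted p = 0.965), KA+NBP against KA (adjusted p = 0.602) or KA+NBP against sham (adjusted p = 0.158), though in the last it passed upward without KA+NBP replicate 1 (adjusted p = 0.00816) or replicate 3 (adjusted p = 0.00102) and downward without KA+NBP replicate 2 (adjusted p = 5.16e-07). Kl, also on that list, did not stand out in a single library. It was at 27.7 ± 3.66 CPM in sham, 10.2 ± 1.05 in KA and 32.4 ± 7.69 in KA+NBP. It fell by 1.44 (SE 0.18) and rose by 1.67 (SE 0.18) in the first 2 comparisons, without overlap of the groups in either. Cd74 of antigen-presenting cells was at 44.0 CPM in KA+NBP replicate 2 and 14.1 to 22.0 in KA, and the leukocyte gene Jchain at 18.9 and 0.432 to 2.83. The 7 leukocyte markers tested did not pass in KA+NBP against KA (camera adjusted p = 0.251), except without KA+NBP replicate 2 (adjusted p = 0.00168). Red blood cell genes were highest in KA+NBP replicate 1, with Hba-a1 at 53.1 CPM, and the list did not pass in KA against sham (adjusted p = 0.321) or KA+NBP against KA (2 of 6 higher, 4 over the list alone, adjusted p = 0.147), except without KA+NBP replicate 3 in the latter (adjusted p = 0.0130). Called red blood cell genes there numbered 6 higher and 1 lower without KA+NBP replicate 2, 5 higher without KA+NBP replicate 3 and 0 without any other KA or KA+NBP library.

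The other lists at the preset correlation in KA+NBP against sham had small medians. They were microglia (0.26, adjusted p = 0.0274), immediate early (-0.15, adjusted p = 0.0348), neuropeptide (0.33, adjusted p = 0.0117), voltage-gated channel (-0.05, adjusted p = 0.0394), antioxidant (0.08, adjusted p = 0.0417), heat shock (0.19, adjusted p = 0.00318), ribosomal (0.04, adjusted p = 0.0465), cholesterol (-0.13, adjusted p = 0.00315) and glucocorticoid-responsive genes (0.20, adjusted p = 0.0184), each with adjusted p = 0.778 with an estimated correlation. Without KA+NBP replicate 2 the heat shock (0.14, adjusted p = 0.00848), cholesterol (-0.13, adjusted p = 0.0491) and glucocorticoid lists (0.28, adjusted p = 7.83e-04) passed in the same direction, and of the others microglia genes (adjusted p = 8.33e-04) passed downward and voltage-gated channels (adjusted p = 0.0304) upward. Immediate early (adjusted p = 0.203), neuropeptide (adjusted p = 0.772), antioxidant (adjusted p = 0.384) and ribosomal genes (adjusted p = 0.912) did not pass without it. Without sham replicate 1 only the heat shock and glucocorticoid lists of these 9 still passed, with adjusted p = 0.0567 for cholesterol and neuropeptide, adjusted p = 0.140 for antioxidant, adjusted p = 0.276 for channel, adjusted p = 0.279 for microglia, adjusted p = 0.440 for ribosomal and adjusted p = 0.797 for immediate early genes. Calls were also lost without sham replicate 2 for ribosomal (adjusted p = 0.166) and glucocorticoid genes (adjusted p = 0.20), and without sham replicate 3 for antioxidant genes (adjusted p = 0.0584) and channels (adjusted p = 0.123). With the replicate block the ribosomal list did not pass (adjusted p = 0.0647), while oligodendrocyte precursor and circadian genes did (adjusted p = 0.0354 each). Immediate early genes lost theirs without KA+NBP replicate 1 (adjusted p = 0.117), and heat shock (adjusted p = 0.144) and glucocorticoid genes (adjusted p = 0.357) without KA+NBP replicate 3.

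The tests of the next pattern were all chosen after the position of KA+NBP replicate 2 was seen. That library lay at 58.1 between sham and KA, while replicates 1 and 3 lay within the sham range. KA+NBP replicate 2 was not intermediate throughout. On the second principal component it lay at -34.2, and the other libraries between -14.5 and 19.5. Its median for choroid plexus markers, relative to the sham mean, was 2.27, against -0.917 to 0.300 in the other libraries. It was also highest for ependymal (1.11, others -0.358 to 0.662), striatal (0.850, others -0.0772 to 0.326) and thalamic markers (0.348, others -0.0706 to 0.120). The same held for leukocyte markers (3.35, others -0.820 to 2.16), while neocortical markers, at -0.258, lay within the range of the other libraries. Whether this library held more of other tissues was not tested. The lowest KA position was 93.2, but the genes of that axis were chosen with the KA labels, so this value does not decide on a swap of labels with a KA library. On the first principal component of all tested genes the KA libraries lay at 52.1, 52.6 and 61.1, KA+NBP replicate 2 at 25.8 and KA+NBP replicates 1 and 3 at -42.4 and -45.0. No KA library lay with KA+NBP replicates 1 and 3 there, while a swap with a treated mouse that lies with KA stays open. On the sham to KA axis a KA mouse carrying this label cannot be told apart from a treated mouse. There the 3 KA libraries give a 95% prediction interval of 55.8 to 141 that holds 58.1. The same limit on the choice of genes applies. On the first principal component KA+NBP replicate 2, at 25.8, lay below all 3 KA libraries. No interval was made for that component, so a KA mouse with this label stays open. RNA of 1 of these KA libraries mixed into another library stays open. If that library had the mean sham profile, which was assumed and not measured, astrocyte markers would need 64.0, 48.9 or 51.2% of it and microglia markers 29.6, 25.4 or 28.7%, with a smallest difference of 22.4 points (3.90 to 36.1). A treatment effect that varies between mice, or KA that left no lasting change in KA+NBP replicates 1 and 3, was not tested and stays open.

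Of the tests of the rise of glial and fall of neuronal genes in KA, the one on neuronal share was chosen only after the result was seen. A lower share of neuronal RNA alone would raise all other cell types by the same factor. The median of microglia markers exceeded that of oligodendrocyte genes by 1.48 (bootstrap interval 1.10 to 2.12). Relative to the sham mean, microglia medians were 1.76, 1.79 and 1.65 in KA replicates 1, 2 and 3. Oligodendrocyte medians were 0.384, 0.381 and 0.0562 in the same libraries. For these lists the values argue against a lower neuronal share as the sole cause. A change in the number of the cell types that rose, in place of their state, stays open in bulk RNA. The gap between activated microglia genes and voltage-gated channels was 3.65 (2.35 to 4.58) before removal of a trend on GC content and transcript length. It was 3.13 (1.89 to 4.14) after removal, with 85.6% kept. The values argue against a GC content or length bias as the main cause of this gap. Most of the gap is the activated microglia median of 3.27, so the test cannot decide on the fall of neuronal genes.

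For complement, no test was chosen after the result was seen. The 18 complement genes raised in KA had a median of -1.84 in KA+NBP against KA, and 10000 random lists of genes raised as much had a median of -1.62 (-1.92 to -1.43). The real value was at percentile 7.44, inside the range of the random lists. A fall particular to complement and the general fall of genes raised in KA cannot be told apart, because 18 genes leave this range wide.

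The splits were planned before the data were seen. The 6 libraries of a comparison divide into 3 and 3 in 10 ways, and 10 splits cannot give a share under 0.05. In KA against sham 1 split, the real one, called 4961 genes and the highest other 0, and 1 split gave 27 lists with 26 as the highest other. In KA+NBP against KA 1 split gave 3355 genes, with 0 as the highest other, and 4 splits gave at least the real 26 lists, with 29 as the highest other. In KA+NBP against sham all 10 splits gave at least the real 0 genes, with 1 as the highest other, and 9 gave at least the real 15 lists, with 30 as the highest other.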
